A study of Mus musculus with 86 samples.

How the data were processed

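The series holds 86 mouse samples. Oocytes of the Mll2 knockout (KO) and wild type (WT), collected as grown germinal vesicle (GV) oocytes at day 21, were profiled by post-bisulfite adaptor tagging (PBAT, whole-genome bisulfite sequencing for small samples) in 3 libraries per genotype of 100 oocytes each, and by RNA sequencing of 4 single oocytes per genotype. Low-input chromatin immunoprecipitation sequencing (ChIP-seq, 250 oocytes per library) gave H3K4me3, H3K27ac and H3K27me3 at day 5 (non-growing oocytes) and day 25 (GV oocytes), and H3K4me3 also at day 10 (growing oocytes) and day 15 (GV oocytes). Bisulfite sequencing of ChIP input DNA covered days 5, 10, 15 and 25 and, at day 25, the double knockout of Dnmt3a and Dnmt3b (DKO) with its WT. H3K4me3 ChIP-seq was also made in DKO and WT oocytes, and in embryonic stem cells (ESC) for technical work.

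Per the submitters' processing notes, reads were trimmed with Trim Galore 0.4.2, and Bowtie2 2.2.9, HISAT2 2.0.5 and Bismark 0.16.3 were used with the mouse build GRCm38. The deposited bisulfite files hold counts of methylated and unmethylated calls for each CpG position and strand, with no minimum on coverage. The deposited 2 kb and 5 kb window tables hold a signal in RPM (reads scaled to the total of the column). They have 1 column per group, made by the authors from the pooled reads of its libraries. The 2 kb table of technical libraries has 1 column per library instead. In every such column, whole reads could be recovered for 100% of values within a tolerance of 0.05 read, which gave the depth. The deposited table of methylated and unmethylated domains holds RPM per domain, not corrected for length, in 1 pooled column each for DKO and WT. The deposited H3K27ac peak table holds RPKM (reads scaled to peak length and to the total) in pooled columns. The deposited RNA table holds RPKM per transcript in 1 column per genotype, corrected by the authors for DNA contamination per the file name. How the authors called domains and peaks, and how they joined the single oocytes, is not stated in the labels.

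Samples were grouped by the labels alone. For RNA these give both Mll2 genotypes as floxed/floxed, with Gdf9 positive in KO and negative in WT. Replicate numbers were checked for pairing of KO and WT by correlating the deviations of tiles from their genotype's mean. The same-numbered pairs gave 0.0865, 0.0346 and 0.276, all positive, against -0.243 to 0.179 for other pairs. This leaves open whether the numbers mark a pairing or a batch. Replicates were treated as unpaired in the main tests, and a block by number was tried as an alternative. With the block 31583 tiles, 549 promoters and 7770 gene bodies were called, against 5080, 377 and 5706 without it. The labels do not say whether libraries came from separate animals, so p-values measure only the spread between samples.

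Deposited transcripts carry no gene names. A name was taken from the RefSeq annotation of GRCm38.p6 when a deposited transcript and a gene overlapped by at least 0.5 of their joint length; the strand and the RNA value came from the best-matching transcript. This named 14237 genes out of 33437 transcripts, among them 12909 of 21631 protein-coding genes (59.7%); 438 ambiguous genes were left out. Promoters were taken as 1 kb either side of the transcription start and gene bodies as the rest of the gene from 1 kb past the start. Calls on the 19 autosomes and X were summed per library over the whole genome, the deposited domains (37272 methylated, 52452 unmethylated), tiles of 10 kb, promoters and gene bodies. Regions with at least 20 calls in every library were tested.

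Methylation of single groups of libraries was compared by exact two-sided permutation tests. With 3 libraries against 3, or 3 against 2, the smallest possible p is 0.1. Tiles, promoters and gene bodies were tested with edgeR 4.0.16 in R 4.3.3, by the quasi-likelihood test for bisulfite counts with 1 term per library and the genotype effect on methylated calls, and called at a Benjamini-Hochberg adjusted p under 0.05. The alternative tool was limma 3.58.1 on the logit of methylation. Tables were made with Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3, and figures with matplotlib 3.10.9. Each test was tested on simulated data with 200 changed regions and the estimated spread of the real libraries, which was 0 for Dnmt3ab tiles, so counting error alone was simulated there. The changes were falls in regions of intermediate to high methylation, so recovery of rises from low levels was not simulated. Binomial and Poisson intervals are at the 95% level (Clopper-Pearson for shares of calls); they cover counting error only.

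ChIP columns were pooled over libraries, so their values were compared with no test: log2 of the ratio of RPM with a pseudocount of 0.1 RPM, over windows or promoters with a mean of at least 1 RPM. For a promoter, the RPM of its windows was averaged. RNA was compared as log2 of the ratio of RPKM with a pseudocount of 1, over genes with a mean of at least 1 RPKM, with no test since each genotype had 1 column. The median of each gene list was placed among 10000 random lists of the same size, matched on level in 20 bins, and its percentile is given; genes are not independent replicates, so a percentile is no p-value. It was tested on simulated data: a list of genes raised by 1 on the log2 scale reached percentile 100, and one left alone 45.8.

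The tests, the alternatives, 18 gene lists and the rule for named genes were fixed before the data were examined. The lists were 2-cell stage embryo genes, DNA methylation machinery, H3K4 demethylases, H3K4 methyltransferases with COMPASS subunits, Polycomb subunits, developmental transcription factors, housekeeping genes, genes imprinted by maternal or by paternal germline methylation, meiotic maturation genes, meiotic prophase genes, pluripotency genes, oocyte genes, p53 targets with apoptosis genes and ribosomal proteins, and markers of granulosa cells, of theca and stromal cells, and of blood and immune cells. The rule took, among called promoters and gene bodies whose KO libraries all lay beyond all WT libraries, the 10 largest rises and 10 largest falls, for tiles, windows, domains and peaks the 3 largest each way, and for RNA the 12 largest each way at a mean of at least 5 RPKM. Symbols of predicted genes (Gm with a number, or ending in Rik) were skipped for promoters, gene bodies and RNA; tiles, windows, domains and peaks were taken by position, with any gene they overlap. Not every gene the rule took is named in the text. Because the ChIP columns were pooled, the rule was changed there to the largest differences with no call, and up to 3 genes of each list (the 2 largest changes and the largest in the other direction) were named as its examples, beside Kmt2b (the gene of MLL2), Dnmt3a, Dnmt3b and Dnmt3l.

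Alternatives were other minimums of calls (10 or 50), a difference of at least 10 percentage points, limma, autosomes alone, the block by replicate number, leaving out each library, means over tiles, positions with at least 3 calls, other pseudocounts and filters, centring or quantile scaling of the ChIP columns, and median in place of mean density. Other splits of the 6 PBAT libraries into 3 and 3 were also run. Left out were the Mll2 KO and WT H3K4me3 ChIP libraries, the epiblast libraries at embryonic day 6.5 and the DKO inputs, for which no column was at hand; they were not analysed here.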

Results

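DNA methylation at CpG positions was measured in PBAT libraries of Mll2 KO and WT oocytes at day 21, with 3 libraries of 100 oocytes per genotype. The KO libraries held 74.3 to 81.0 M CpG calls and the WT libraries 97.0 to 102 M (M stands for mega), at a mean of 2.54 to 3.14 calls per covered position. Bisulfite libraries of ChIP input DNA, from 250 oocytes each, held 1.23 to 2.82 M calls. There were 1 at day 5, 2 at day 10, 1 at day 15 and 1 at day 25 for the course of oocyte growth, and 3 DKO against 2 WT at day 25 for Dnmt3a and Dnmt3b. RNA came from 4 single oocytes per genotype of Mll2, given as 1 column each, and its read depth is unknown. The pooled H3K4me3 columns stood for 3 libraries and 5.50 M reads at day 5, 2 libraries and 4.58 M at day 10, 2 and 8.06 M at day 15, and 2 and 22.5 M at day 25. H3K27ac had 2 libraries each at day 5 (5.50 M reads) and day 25 (21.5 M), as had H3K27me3 (8.21 M and 22.0 M). H3K4me3 in DKO and WT had 4 libraries each by the labels, with 30.1 and 29.7 M reads in the window table and 42.7 and 40.2 M in the domain table. Since these totals differ, the tables may not pool the same libraries, and the column names do not say which they hold. Pooled columns carry no spread between libraries, so their values are given without a test, as is RNA.

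MLL2, the product of Kmt2b, deposits H3K4me3, and oocytes labelled as its KO were compared with WT in DNA methylation and RNA. Methylated domains, the large stretches that growing oocytes methylate, stood at 75.8% ± 0.840 (SD, n = 3) in KO and 82.8% ± 1.14 (n = 3) in WT, and each KO library was below each WT library. The exact two-sided permutation p for this difference of -7.00 percentage points was 0.1, the smallest that 3 against 3 allows. Unmethylated domains stood at 14.2% ± 3.54 (n = 3) in KO and 12.5% ± 3.89 (n = 3) in WT, with the libraries intermixed (exact permutation p = 0.6). The difference of 1.71 points became -0.488 without WT replicate 3, 0.0885 without KO replicate 1, 3.60 without KO replicate 3 and 3.21 without WT replicate 2. WT replicate 3 had 8.13% in unmethylated domains, and 2.48% at mitochondrial CpGs where the other 5 libraries had 45.9% to 54.5%. Over all calls, KO had 36.5% ± 2.17 (n = 3) and WT 38.2% ± 3.07 (n = 3), a difference of -1.76 points that was smaller than the spread between libraries (exact permutation p = 0.4). It was -3.48 without WT replicate 3, -2.66 without KO replicate 1, -0.551 without KO replicate 3 and -0.535 without WT replicate 2.

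**Figure D1:**
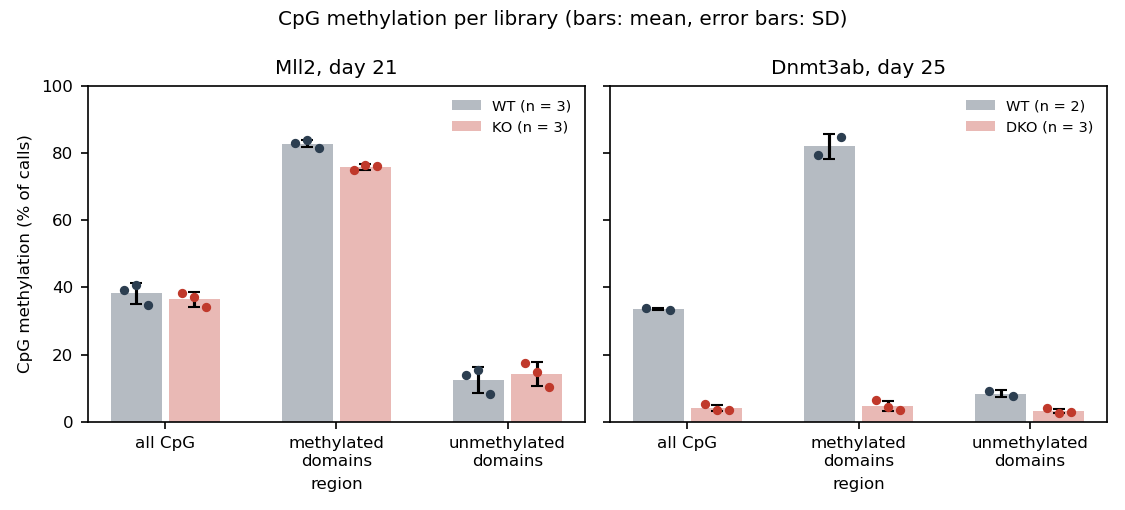
CpG methylation in percent of calls, for all CpG positions, methylated domains and unmethylated domains, in Mll2 KO and WT oocytes at day 21 and in Dnmt3ab DKO and WT oocytes at day 25; points are libraries, bars are means and error bars SD. Methylated domains stand at 75.8% in Mll2 KO against 82.8% in WT, and at 4.78% in DKO against 82.0%.

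Among tiles of 10 kb, the largest rise in KO lay over 1700049E15Rik (chromosome 6, 147690001 to 147700000, from 13.2% in WT to 67.3%). Next were tiles over Mta3, a chromatin remodelling subunit (chromosome 17, 83810001 to 83820000, 20.0% to 71.7%), and over Cc2d2a, a gene of the cilium base (chromosome 5, 43700001 to 43710000, 22.5% to 72.9%). The 3 largest falls lay over Ccdc172 (chromosome 19, 58530001 to 58540000, from 91.6% to 12.3%, and 58550001 to 58560000, from 90.4% to 13.8%) and over Zfp512 (chromosome 5, 31460001 to 31470000, 93.1% to 16.5%). In all, 5080 of 252604 tiles changed, 1061 up by a median of 26.1 points and 4019 down by a median of -27.7 points. Of the 48849 tiles in methylated domains, 25 rose and 2326 fell, and of the 106533 in unmethylated domains, 446 rose and 35 fell. Median WT levels of 89.1% and 12.5% in these tiles limit rises in the methylated and falls in the unmethylated domains. Groups did not overlap in all 5080 changed tiles and in 23.2% of the tiles tested, where chance gives 10%. The count was 2422 without KO replicate 1, 1583 without KO replicate 2 and 2977 without KO replicate 3. It was 1689 without WT replicate 1, 2455 without WT replicate 2, and 31583 with a block by replicate number. In simulated data the test recovered 4.48%, 47.8% and 98.5% of falls of 10, 20 and 40 points, with 1 false call.

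Called promoters rose more often than they fell: 311 rose and 66 fell among 13876 tested. The median over tested promoters was 3.20% in WT, so most had little to lose. Where WT stood at 50% or more and RNA differed by less than 0.5 on the log2 scale, 425 promoters changed by a median of -8.52 points. The largest rise was at Zfp410, a zinc finger activator of a chromatin remodeller gene (chromosome 12, 84315510 to 84317510), from 10.0% ± 0.614 (SD, n = 3) in WT to 69.6% ± 6.96 (n = 3) in KO (adjusted p = 2.05e-06). Its RNA was 22.7 RPKM in WT and 6.00 in KO. At Rpf2, a ribosome assembly factor (chromosome 10, 40246039 to 40248039), methylation rose from 6.21% ± 1.88 to 59.4% ± 2.60 (n = 3 each, adjusted p = 2.53e-06), beside RNA of 49.3 RPKM in WT and 18.0 in KO. Alad, an enzyme of heme synthesis (chromosome 4, 62519063 to 62521063), rose from 10.6% to 62.8%. The zinc finger gene Zfp788 (chromosome 7, 41632531 to 41634531) rose from 4.05% to 53.7%, with RNA of 16.5 RPKM in WT and 1.27 in KO. The nuclease gene Endod1 rose from 4.41% to 51.0% while its RNA was 23.4 RPKM in WT and 23.5 in KO. Plpbp (12.9% to 64.4%), the homeobox gene Prrx2 (15.4% to 66.5%), Fam172a (33.6% to 84.2%), Zfp808 (4.47% to 51.2%) and Zc3h12b (11.5% to 57.2%) completed the 10 largest rises.

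The largest falls were at promoters that WT oocytes methylate. Lgals9, which encodes a galectin (chromosome 11, 78983924 to 78985924), fell from 89.8% ± 2.01 to 14.6% ± 8.71 (n = 3 each, adjusted p = 3.12e-06). Wdfy4, a gene of antigen presentation by dendritic cells (chromosome 14, 33192855 to 33194855), fell from 75.6% ± 3.19 to 12.3% ± 0.555 (adjusted p = 3.41e-05). The vesicular amine transporter gene Slc18b1 fell from 82.1% to 36.5% and Art4 from 57.2% to 14.9%. Actr1b, a dynactin subunit, fell from 74.8% to 34.0%, and Pcolce, which aids collagen processing, from 84.8% to 47.3%. Tent5d (85.3% to 47.9%), the phospholipase gene Plch1 (79.3% to 42.7%), the cytokine gene Il18 (67.3% to 32.1%) and Samd15 (86.7% to 51.6%) followed. Promoters that rose had a median of 3.60% in WT and rose by a median of 14.1 points, and those that fell had 62.5% and changed by -25.7 points.

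Among the fixed lists, promoters of 4 lists had a call over all genes tested. In the DNA methylation machinery Tet3, the oxidase of methylcytosine in oocyte and zygote, fell from 52.2% ± 3.20 to 23.2% ± 3.49 (n = 3 each, adjusted p = 0.00354). Adjusted over the list alone, 2 of 13 genes fell, with Dnmt3b at 86.0% in WT and 70.3% in KO (adjusted p = 0.135 over all genes). Gdf9, a growth factor of the oocyte, was the 1 of 24 oocyte genes that rose, from 1.395% ± 0.657 to 7.80% ± 2.36 (adjusted p = 0.00124). Adjusted over the list alone, 2 rose, Gdf9 and the oocyte transcription factor gene Nobox. CpG calls over the Gdf9 promoter, scaled per M calls of the library, were 13.1 to 15.0 in KO libraries and 4.35 to 7.55 in WT libraries. The KO is labelled Gdf9 positive, so extra copies of Gdf9 sequence may give part of these methylated calls. Hprt, a housekeeping enzyme of purine salvage, rose from 2.80% to 11.4% (adjusted p = 0.0231), and Bcl2l11, an apoptosis gene of the p53 list, from 9.18% to 27.9% (adjusted p = 0.00151). Each was the 1 member of its list called over all genes and adjusted over the list alone. Promoters of the other 14 lists gave 0 calls by edgeR over all genes and 0 by limma among 172 genes tested, of which 18 had an unadjusted p under 0.05. Adjusted over the list alone, 1 of 15 granulosa cell markers rose, the inhibin subunit gene Inha. Kmt2b itself had 7.34% in WT and 7.24% in KO, Dnmt3a 7.48% and 9.22%, and Dnmt3l 11.3% and 12.5%.

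The promoter count of 377 was 227 without KO replicate 1, 199 without KO replicate 2 and 219 without WT replicate 1, 219 by limma and 251 at a change of 10 points or more. Groups did not overlap in 376 of the called promoters and in 18.3% of those tested, where chance gives 10%. In simulated data the test recovered 4.48%, 50.7% and 100% of falls of 10, 20 and 40 points, with 2 false calls. These falls were made at promoters of intermediate to high methylation. The rates therefore do not cover rises from low levels, which most called promoters were.

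Gene bodies, which oocytes methylate along transcribed units, lost methylation widely: 5406 fell and 300 rose among 13894 tested. Hnrnph2, an RNA-binding protein gene (chromosome X, 134602180 to 134607060), fell from 93.5% ± 2.41 (SD, n = 3) in WT to 15.8% ± 6.05 (n = 3) in KO (adjusted p = 4.36e-05), with RNA of 26.97 RPKM in WT and 1.21 in KO. The exonuclease gene Eri2 (chromosome 7, 119783826 to 119793057) fell from 94.5% to 23.1%, with RNA of 26.0 and 0.545 RPKM. The coiled-coil gene Ccdc172 (chromosome 19, 58512986 to 58553104) fell from 84.7% ± 0.825 to 13.98% ± 2.51 (n = 3 each, adjusted p = 8.53e-06), with RNA of 24.9 and 0.915 RPKM. The esterase gene Esd (90.5% to 15.4%, RNA 33.0 and 4.09 RPKM) and Commd8 (87.2% to 16.6%, RNA 10.6 and 1.42) fell too. So did Ssr4, a subunit of the endoplasmic reticulum translocon complex (83.7% to 13.5%, RNA 15.3 and 4.82) and Mbd1, a reader of methylated CpG (84.2% to 14.3%, RNA 3.74 and 0.489). Dhrs11 (89.4% to 14.3%), the telomere maintenance gene Ctc1 (87.8% to 15.1%) and the deubiquitinase gene Yod1 (87.8% to 16.9%) were the rest of the 10 largest falls.

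The largest rises were at gene bodies with low levels in WT. The keratin gene Krt79 (chromosome 15, 101929332 to 101939323) rose from 9.28% ± 2.08 to 54.3% ± 3.59 (n = 3 each, adjusted p = 3.24e-05), with RNA of 0.358 RPKM in WT and 5.34 in KO. The brush border myosin gene Myo7b rose from 15.7% to 44.5%, with RNA of 0.339 and 5.18 RPKM. Cc2d2a rose from 31.5% to 65.4% (RNA 0.836 and 2.60 RPKM), and the sugar transporter gene Slc50a1 from 28.1% to 70.3%. Tmem176a (22.9% to 56.4%), Epdr1 (15.1% to 45.8%), the endolysosomal channel gene Tpcn1 (19.6% to 50.3%), Itih5l-ps (34.8% to 64.1%), Nsg2 (19.4% to 47.8%) and the muscle glycogen phosphorylase gene Pygm (28.2% to 56.4%) were the others.

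**Figure D2:**
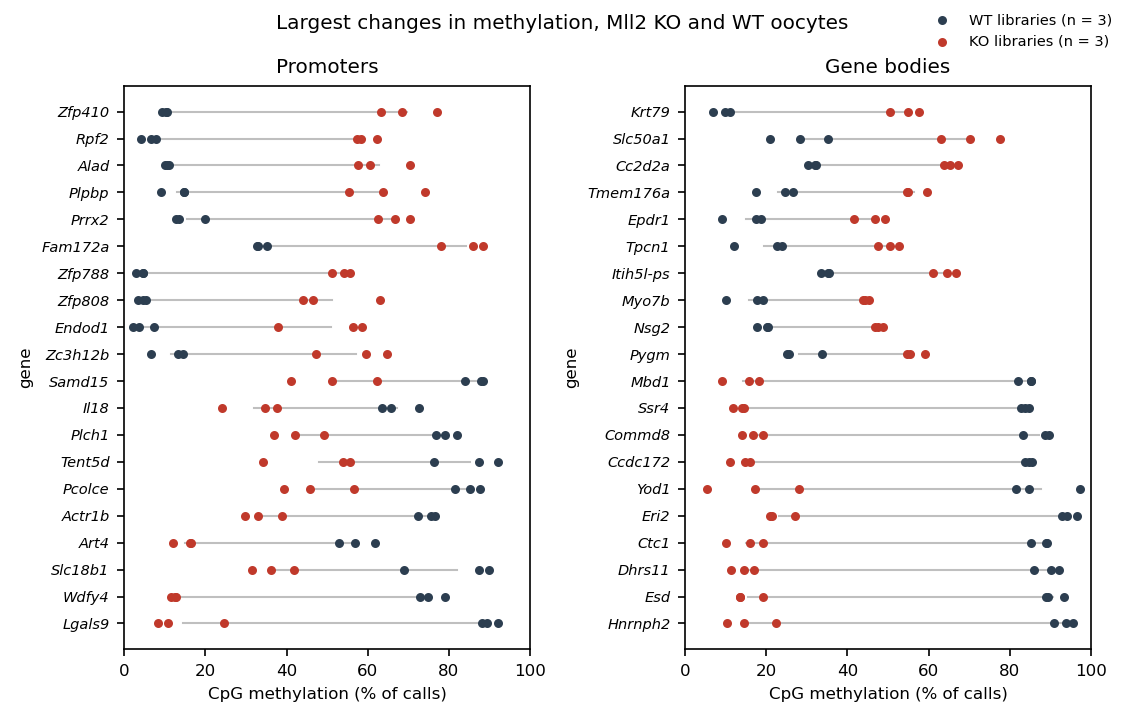
CpG methylation in percent of calls at the promoters (left) and gene bodies (right) with the 10 largest rises and 10 largest falls; each point is a library, 3 of KO and 3 of WT per gene, and lines join the genotype means. Zfp410 goes from 10.0% in WT to 69.6% in KO and Hnrnph2 from 93.5% to 15.8%.

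Meiotic and oocyte genes were among those whose bodies fell. For comparison, 5406 of all 13894 bodies tested fell, and 4678 of 10335 in genes with a mean of at least 1 RPKM. Counts of lists, here and below, that lie near those shares mark no trait of the list. In the meiotic prophase list, 10 of 17 gene bodies fell over all genes, and 11 adjusted over the list alone. Among them were Hormad2, a chromosome axis protein (80.5% to 43.2%), and Mael, which silences transposons (74.2% to 44.9%). Msh5, a recombination gene, rose from 33.1% to 44.9%. Of 23 oocyte genes 10 fell by both adjustments, such as the zona pellucida gene Zp3 (64.4% to 47.7%) and Tle6 of the subcortical maternal complex (68.4% to 50.2%). In the DNA methylation machinery 8 of 13 fell over all genes and 9 adjusted over the list alone. Dnmt3a fell from 65.0% to 52.1% and Dnmt3b from 91.9% to 87.0%, while Dnmt3l had 84.0% in WT and 79.0% in KO (adjusted p = 0.0562). Dppa3, which protects methylation in the zygote, fell from 44.9% to 28.7%. Of 11 pluripotency genes 4 fell by both adjustments, with Zfp42 at 65.4% in WT and 13.6% in KO, and Dppa4 at 88.6% and 49.4%. Among genes imprinted by maternal germline methylation, 14 of 18 fell and 1 rose over all genes, and 15 fell and 1 rose adjusted over the list alone. Cdh15 fell from 76.3% to 52.9%, Zrsr1 from 85.8% to 74.7%, and Sgce rose from 14.3% to 22.6%. Of the 5 imprinted by paternal methylation, Meg3 fell from 75.5% to 67.3%, the 1 call by both adjustments.

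Ribosomal protein genes fell in 7 of 19 cases by both adjustments, among them Rps15 (68.5% to 36.4%) and Rpl27 (77.5% to 63.1%). Housekeeping genes fell in 9 of 14 by both, for example Tubb5 (59.8% to 44.1%) and the chaperone gene Hsp90ab1 (86.3% to 71.1%). H3K4 methyltransferases and COMPASS subunits fell in 7 of 15 over all genes and 8 adjusted over the list alone, with Prdm9 (78.4% to 55.7%), Smyd3 (67.1% to 54.7%) and Kmt2b (89.2% to 82.6%). H3K4 demethylases fell in 5 of 8 by both, with Kdm1b (79.9% to 66.2%) and Kdm2b (86.6% to 77.0%). Of 16 Polycomb subunits 5 fell, such as Cbx2 (72.2% to 62.6%) and Ring1 (80.3% to 70.7%), and Cbx7 rose (35.5% to 44.7%), by both adjustments. Meiotic maturation genes fell in 7 of 14 over all genes and 8 adjusted over the list alone, with Ccnb1 (69.5% to 56.0%) and Cdc25b (83.5% to 76.2%). The p53 targets with apoptosis genes fell in 5 of 19 by both, with Bax (92.7% to 67.3%) and Ccng1 (91.6% to 80.4%). Of 18 developmental transcription factors Tbx2 rose (8.98% to 20.7%) and Gata4 fell (42.2% to 35.5%) over all genes by edgeR. Adjusted over the list alone 0 were called, with 4 at an unadjusted p under 0.05 and 0 calls by limma. Granulosa cell markers fell in 3 of 17 over all genes, namely Cyp11a1 (60.03% to 53.7%), Nr5a2 (77.5% to 69.3%) and Serpine2, and 2 of those adjusted over the list alone. Of 3 blood markers, Pecam1 fell (88.9% to 83.6%) by both. Bodies of 2-cell stage genes and theca markers, 10 genes tested, gave 0 calls by edgeR, 0 by limma, 0 at an unadjusted p under 0.05 and 0 adjusted over the list alone.

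Over all gene bodies tested, the median change was -4.40 points, and of those that fell -7.03 points. A change of at least 10 points was seen in 1682 of the 5706 called. The count was 3480 without KO replicate 1, 3695 without KO replicate 2, 3268 without WT replicate 1 and 3762 without WT replicate 2. Groups did not overlap in 5688 of those called and in 55.0% of gene bodies tested, where chance gives 10%. In simulated data the test recovered 67.2%, 100% and 100% of falls of 10, 20 and 40 points, with 9 false calls.

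RNA of a set of oocyte genes was lower in KO and markers of other ovarian cells were higher, in 1 column per genotype and without a test. Kmt2b was 14.02 RPKM in WT and 10.9 in KO (log2 -0.33), so RNA of the whole gene does not show its loss, and the deleted part was not examined. The lowest ratios were those of Gsto2, a glutathione transferase (43.2 to 0.104 RPKM, log2 -5.32), Eri2 (-4.13), Ccdc172 (-3.76), the profilin gene Pfn4 (22.2 to 0.765 RPKM, -3.72) and Hnrnph2 (-3.66). Mocs2, of molybdenum cofactor synthesis, was 63.7 RPKM in WT and 6.21 in KO (-3.17). Xlr4b (55.8 to 5.47 RPKM), Tmem47 (16.3 to 1.034), Lrif1 (23.3 to 2.07), Fmr1nb (13.2 to 0.838), Zfp788 (16.5 to 1.27) and the meiotic recombination gene Tex15 (30.6 to 3.24) came next, between -3.13 and -2.90. Highest in KO relative to WT were Fshr, the receptor of follicle-stimulating hormone (0.0123 to 12.4 RPKM, log2 3.72), and the keratin gene Krt76 (0.713 to 15.8, 3.29). The splicing factor gene Prpf39 (41.6 to 373 RPKM, 3.14), Foxp2 (0.396 to 10.4, 3.03) and the matrix protein gene Sparc (0.702 to 12.8, 3.02) came next. Among those that followed were the gap junction gene Gja1 (0.825 to 11.05 RPKM), the inhibin subunit gene Inha (0.930 to 10.3), Mgst1 (0.834 to 9.55), Eri1 (7.78 to 39.2), Cntn6 (4.49 to 24.0) and Tmem176b (1.45 to 9.74).

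**Figure D3:**
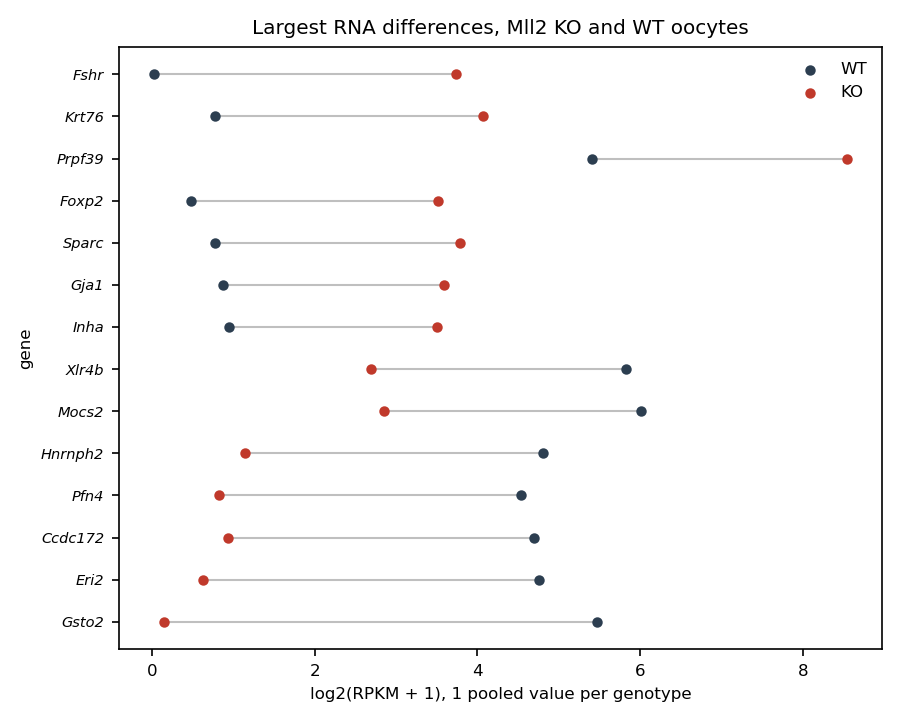
RNA of the 7 genes with the lowest and the 7 with the highest ratio of KO to WT, as log2 of RPKM with 1 RPKM added, 1 value per gene and genotype from 1 column each. Lines join the genotypes of a gene, and the log2 ratio runs from -5.32 at Gsto2 to 3.72 at Fshr.

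Oocyte genes had a median log2 of -0.39, with 18 of 23 below 0, at percentile 0 of matched random lists. Zp2, of the zona pellucida, was 4273 RPKM in WT and 2292 in KO, the protease gene Astl 287 and 148, and the transcription factor gene Lhx8 25.2 and 42.1. Granulosa cell markers had a median of 1.16 over the 8 kept by the filter on mean RPKM, and theca and stromal markers 2.15 over the 5 kept, but this filter takes members by their KO value, since 4 and 0 of them reached 1 RPKM in WT. With a pseudocount of 0.1 RPKM these medians were 1.79 and 2.99. Over all markers with a value, 17 of granulosa cells had a median of 0.49 with 14 above 0, and 7 of theca and stromal cells 1.82 with 7 above 0. Their percentiles among lists matched on the WT level alone were 99.99 and 100. Examples were Col1a2 (0.455 to 7.05 RPKM), Dcn (0.426 to 5.61) and Acta2 (0.937 to 3.35). Not all granulosa genes were higher. Amh was listed at 0 in both, Cyp11a1 was 0.824 RPKM in WT and 0.780 in KO, and Serpine2, which oocytes also held, 215 and 148. Foxl2 was higher in KO but low in both, at 0.0261 and 0.485 RPKM. Ribosomal proteins had a median of 0.32, with 18 of 19 above 0 (percentile 99.97), for example Rpl13 (8.04 to 17.2 RPKM) and Rpl13a (69.6 to 109). Meiotic prophase genes stood at -0.12 (percentile 3.81), with Mlh3 at 5.35 and 1.30 RPKM and Tex11 at 12.2 and 19.5, and at 0.03 over those with a mean of at least 5 RPKM. Housekeeping genes had -0.12 (3.67), with Polr2a at 9.65 and 20.6. Pluripotency genes had a median of -0.21 (5.67), or -0.12 (2.29) over all 11 with a value, and Dppa4 was 12.8 RPKM in WT and 3.07 in KO. Within the DNA methylation machinery (0.03, percentile 38.5), Dnmt3a was 94.2 and 68.5 RPKM, Dnmt3b 5.61 and 5.93, Dnmt3l 78.7 and 66.3, and Tet1 6.35 and 10.2.

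Medians of the other lists lay between -0.03 and 0.20. For 2-cell stage genes it was 0.08 over the 6 kept (percentile 56.9), with Zscan4d at 15.0 and 33.9 RPKM and Tcstv3 at 51.6 and 19.3. Over all 8 with a value, matched on the WT level alone, it was 0.33 (percentile 98.1), with 5 above 0. H3K4 demethylases had -0.03 (26.9), with Kdm5b at 9.28 and 4.05, and H3K4 methyltransferases -0.03 (17.8), with Smyd3 at 16.2 and 9.10. Polycomb subunits had 0.04 (38.8), and developmental transcription factors 0.20 (65.5). Genes imprinted by maternal methylation had 0.00 (26.1), with H13 at 13.4 and 20.0 RPKM, meiotic maturation genes 0.12 (77.4), with the spindle checkpoint gene Bub1b at 387 and 258, and p53 targets 0.09 (51.4). The 1 expressed gene imprinted by paternal methylation had 0.13, and the 2 expressed blood markers 0.11. The globin gene Hbb-bs was listed at 0 in both. Over 10467 genes the median log2 was 0.07, 94.0% lay within 1, 327 were at 1 or above and 298 at -1 or below. WT and KO had a Spearman correlation of 0.961 across genes, which are not independent replicates.

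Gene bodies fell most where RNA was lower. For the 53 genes with a log2 RNA ratio of -2 or less, the median change of body methylation was -44.6 points (quartiles -59.1 and -21.5) and 45 were called down, and for the 291 at -1 or less it was -19.2 points. Genes within 0.5 of 0, 8066 of them, had a median of -4.86 points, and the 318 genes at 1 or more 0.662 points, with 36 called up and 29 down. Among bodies at 50% or more in WT, the medians were -47.8 points for 46 genes at -2 or less, -5.14 for 6855 within 0.5 and -3.82 for 99 at 1 or more. Across 10335 genes the Spearman correlation of the 2 changes was 0.211 for gene bodies, and it was -0.0151 for promoters across 10269. Promoters were called in 26 of 289 genes at -1 or less (21 up), in 151 of 8035 within 0.5 (128 up) and in 11 of 305 at 1 or more (11 up). The correlation over all promoters, which had a median of 2.99% in WT, does not show this difference in calls. Genes are not independent replicates.

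**Figure D4:**
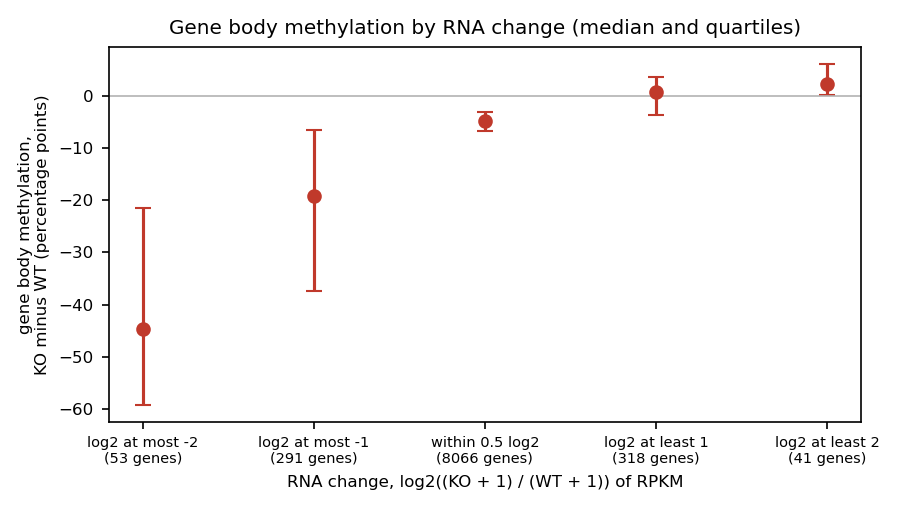
Change of gene body methylation, KO minus WT in percentage points, by class of RNA log2 ratio of KO to WT; points are medians over the genes of a class and bars the quartiles; classes differ in their WT level. The median runs from -44.6 points in genes at -2 or less to 0.662 points in those at 1 or more.

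Oocytes without Dnmt3a and Dnmt3b, the de novo DNA methyltransferases, were compared with WT to ask how methylation shapes H3K4me3. Their methylated domains stood at 4.78% ± 1.48 (SD, n = 3) against 82.0% ± 3.72 (n = 2) in WT, and unmethylated domains at 3.18% ± 0.689 against 8.31% ± 1.074. For each of these, and for all calls (4.13% ± 0.940 against 33.6% ± 0.264), DKO libraries were below WT libraries (exact two-sided permutation p = 0.1, the smallest that 3 against 2 allows). Over positions with at least 3 calls the differences were smaller, at -8.78 points over all calls against -29.4, -57.0 against -77.3 in methylated domains and -2.42 against -5.13 in unmethylated ones. A tile over Slc38a7 (chromosome 8, 95840001 to 95850000) fell from 100% to 0.546%. A tile over Rfx2, a factor of ciliary genes (chromosome 17, 56800001 to 56810000), fell from 100% to 1.08%, and that over 2900026A02Rik (chromosome 5, 113120001 to 113130000) from 98.3% to 0%. Of 6528 tiles tested by edgeR 3148 fell, 1004 of them in methylated domains where 1034 were tested, and 4 rose. The 4 were over Filip1l (8.37% to 15.0%), Zc3h7a (7.13% to 13.7%), Runx1, a blood transcription factor (from 0% to 3.86%), and AY036118. The lowest library held 640, 485, 34 and 10265 calls in them, against 31, 24 and 20 in the 3 tiles named as falls. Why the tiles over Filip1l, Zc3h7a and AY036118 were so deep was not examined. The tile over AY036118 (chromosome 17, 39840001 to 39850000, 9.74% to 13.1%, libraries intermixed) was named after its values were seen. With at least 10 calls per library the count was 11741 of 23172 tiles, with at least 50 it was 218 of 561, and with a block by number 1914, all of them falls, so the 4 rises were lost. In data simulated with counting error alone the test recovered 0%, 23.9% and 100% of falls of 10, 20 and 40 points, with 2 false calls.

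H3K4me3 was higher over methylated domains in DKO, at 0.399 RPM per kb against 0.321 in WT (fold 1.25), and lower over unmethylated domains, at 0.406 against 0.45003 (fold 0.903). RPM is a share of reads, and methylated and unmethylated domains held 31.1% and 59.5% of them in DKO and 24.9% and 65.9% in WT. A higher share in 1 class therefore lowers the other, and an absolute fall was not measured. The ratio of methylated to unmethylated domains was 0.983 in DKO and 0.712 in WT, a log2 difference of 0.47 (counting interval 0.46 to 0.47). Of methylated domains 80.9% had a log2 above 0, with a median of 0.26, and of unmethylated domains 22.3%, with a median of -0.13. The highest ratio was at Zp3, the zona pellucida gene (chromosome 5, 135976780 to 135981639, an unmethylated domain), with 83.7 RPM in DKO and 6.71 in WT (log2 3.62). Next to it, over Ssc4d (135959935 to 135975799, a methylated domain), were 71.3 and 7.83 RPM (3.17). Over those 2 domains the DKO bisulfite inputs held 127 to 156 CpG calls per M and the WT inputs 51.1 to 54.4. At the unmethylated domain alone the input calls were 12.8 times those of WT, whose inputs held 21 calls there, beside 12.5 times the H3K4me3. The H3K4me3 ratio there thus did not exceed that of the input. At the methylated domain the ratios were 1.67 and 9.10. The DKO is labelled Zp3 positive, so extra copies of Zp3 sequence may give these reads in part or in whole. The third highest ratio was over Sdk1, a cell adhesion gene (chromosome 5, 141392504 to 141394732, 2.27 and 0.646 RPM). The lowest were on chromosome 12 (25497729 to 25501549, 1.08 and 3.11 RPM), chromosome 9 (19720628 to 19731066, 0.632 and 1.62) and chromosome 14 (19220560 to 19225438, 0.632 and 1.54). By windows of 2 kb the median log2 was 0.41 in methylated and -0.16 in unmethylated domains. The 3 highest windows were those by Zp3, such as 135976001 to 135978000 with 56.98 RPM in DKO and 2.16 in WT. The lowest were on chromosomes 8 (19146001 to 19148000), 19 (51188001 to 51190000) and 9 (43814001 to 43816000).

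As oocytes grew, methylation and H3K4me3 parted between domains. The domains are classed by methylation, and how the authors called them is not stated. If grown oocytes were used, the parting of methylation by day 25 is set by the class and is no independent evidence. Methylated domains held 4.95% methylation at day 5 (exact binomial 95% interval 4.90% to 5.00%), 9.98% and 12.8% in the 2 libraries of day 10, 60.8% at day 15 and 86.9% at day 25 (86.9% to 87.0%). Unmethylated domains held 3.53% at day 5, 3.27% and 4.57% at day 10, 3.90% at day 15 and 7.98% at day 25 (7.93% to 8.04%). Over positions with at least 3 calls, of which these libraries had 8053 to 46318, unmethylated domains held 15.2% at day 5, 8.16% and 12.2% at day 10, 13.9% at day 15 and 20.8% at day 25. Methylated domains there held 7.73%, 9.83% and 13.4%, 47.9% and 74.0%, so these levels depend on the minimum of calls. H3K4me3 over methylated domains, relative to unmethylated ones, was 1.05 at day 5, 0.777 at day 10, 0.747 at day 15 and 0.287 at day 25, where the inputs of the same days had 1.12, 1.06, 1.092 and 1.10. Methylated domains held 28.9% of the H3K4me3 signal at day 5 and 10.4% at day 25, and unmethylated ones 53.2% and 70.4%. H3K27me3 had ratios of 0.688 at day 5 and 0.285 at day 25, and H3K27ac 1.22 and 1.17. For H3K4me3 the amount of antibody was 62.5 or 125 ng at day 5 and 250 ng at days 10, 15 and 25, so the step from day 5 cannot be told apart from it. H3K27me3 had 125 ng on both days, and H3K27ac 125 ng at day 5 and 250 or 62.5 ng at day 25.

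**Figure D5:**
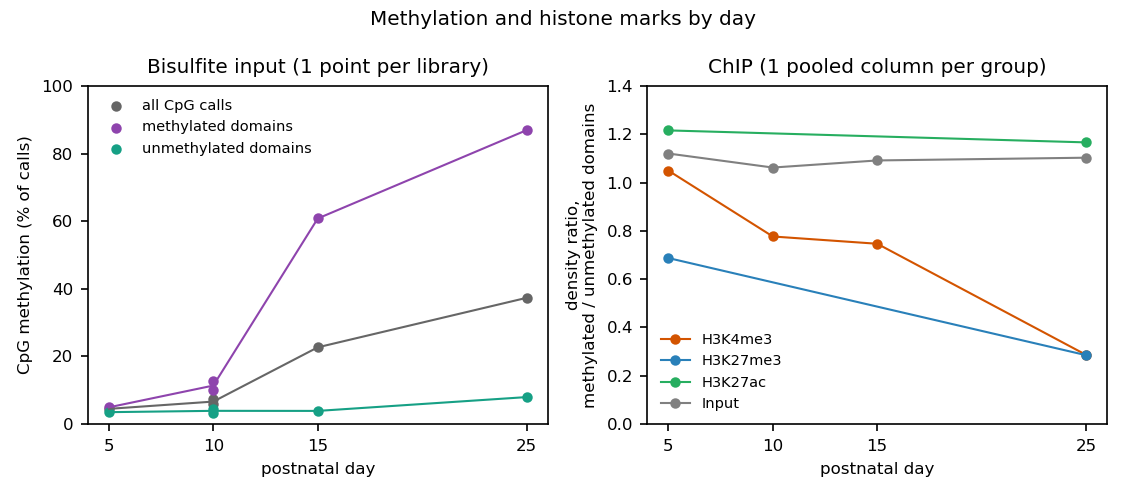
CpG methylation in percent of calls (left, points are libraries) and the ratio of signal density in methylated to unmethylated domains for histone marks and input (right, 1 pooled value per day) at days 5 to 25. Methylated domains go from 4.95% to 86.9% methylation while their H3K4me3 ratio goes from 1.05 to 0.287.

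Windows of 2 kb gave the same division for H3K4me3 between day 5 and day 25. The median log2 was -1.46 in methylated and 0.78 in unmethylated domains, and 0.49 over all 340055 windows kept. Without the filter on RPM these were -1.25, 0.02 and -0.17, so the median over all windows turned. With the filter and each column centred on its median log2, the median over all windows kept was 1.22. Highest against day 5 were windows by Pcsk1n and Eras, an oncogene-like gene of pluripotent cells (chromosome X, 7924001 to 7926000, listed at 0 at day 5 and 5.83 RPM at day 25). Next were windows by Gm35957 (chromosome 4, 119696001 to 119698000, 0 and 5.03) and by Lrrc1 (chromosome 9, 77484001 to 77486000, 0 and 4.89). Lowest were windows over Slco3a1, an organic anion transporter gene (chromosome 7, 74298001 to 74300000, 2.91 RPM at day 5 and 0 at day 25). Windows over Ankrd36 (chromosome 11, 5632001 to 5634000, 2.55 and 0) and Mdh2, of the citric acid cycle (chromosome 5, 135788001 to 135790000, 2.36 and 0) followed. From day 5 to day 10 the median was 0.25, -0.0553 without the filter and 0.87 with each column centred on its median log2. Windows on chromosome 1 (115384001 to 115386000, 0 to 6.55 RPM, and 31150001 to 31152000, 0 to 5.68) were highest. Those over Mad1l1, of the spindle checkpoint (3.64 to 0), and on chromosome 17 (84118001 to 84120000, 3.82 to 0) were among the lowest. From day 10 to day 15 the median was -0.10, 0.13 without the filter and 0.00662 with quantile scaling, with a window over Xpnpep1 at 0 and 2.85 RPM. Windows over Rbmx, an RNA-binding protein gene (2.84 to 0), and Ngef (2.40 to 0) were among the lowest. From day 15 to day 25 it was 0.25, -0.12 without the filter and 0.00 with quantile scaling, with Phka1, of glycogen breakdown (0 to 3.34 RPM), and Cpq (0 to 2.71) among the highest. Cdh17 (1.86 to 0), Arhgef10l (1.74 to 0) and Hip1r (1.74 to 0) were lowest.

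At promoters H3K4me3 had a median log2 of 0.40 from day 5 to day 25, with 10049 of 12891 above 0. With each column centred on its median log2 the median was -0.12, and with quantile scaling -0.0143, so its sign depends on the scaling. The highest were Egflam, of the extracellular matrix (0 to 3.71 RPM), the integrin gene Itga8 (0.182 to 2.60) and Lrp2bp (0.273 to 3.45). Cfap53, a cilium gene (0.364 to 3.56), Magea10 (0.455 to 4.09), Ptprz1, Ehf (0.546 to 4.69), Sri, Ankrd33b and Tctex1d1 were the rest of the 10 highest. Among the lowest were Ssc4d (6.19 to 0.578) and Necab3 (2.27 to 0.222). Samm50, of the mitochondrial outer membrane (3.09 to 0.334), Smarcc2, a chromatin remodelling subunit (3.27 to 0.378), Gpatch4, Nqo2, AB124611, the cohesin gene Stag1 (2.09 to 0.245) and Dmbt1 followed. Dnmt3b went from 3.55 to 0.489 RPM, Dnmt3l from 4.73 to 6.38, Dnmt3a from 0.637 to 1.0898 and Kmt2b from 4.55 to 4.31. The share of H3K4me3 signal at promoter windows was 5.79% at day 5, 10.6% at day 10, 6.33% at day 15 and 7.65% at day 25.

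Granulosa cell markers (median 1.35, percentile 99.9), genes imprinted by paternal methylation (1.63, 99.6) and pluripotency genes (0.94, 99.2) were highest among the lists. Gatm went from 0.455 to 2.25 RPM, Rasgrf1 from 0.728 to 4.43 and Meg3 from 1.00 to 3.94. Klf5 went from 0.728 to 3.51 and Zfp42 from 0.728 to 2.31. Developmental transcription factors had 0.59 (68.6), with Gata6 (0.819 to 4.34 RPM) and Pax6 (1.64 to 4.65), meiotic prophase genes 0.67 (79.5) and theca markers 0.65 (62.5). Ribosomal proteins (0.17, 4.81), genes imprinted by maternal methylation (0.11, 6.63) and oocyte genes (0.11, 7.66) were low among random lists. Cdh15 went from 1.36 to 0.2002 RPM and Zrsr1 from 1.46 to 0.289. The machinery of DNA methylation had 0.22 (40.2), H3K4 demethylases 0.13 (20.0) and H3K4 methyltransferases 0.26 (45.8). Polycomb subunits had 0.16 (15.3), housekeeping genes 0.25 (19.01), meiotic maturation genes 0.36 (79.5) and p53 targets 0.34 (31.5). The 1 promoter kept of 2-cell stage genes had 0.56 and that of blood markers -1.37.

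H3K27ac at promoters had a median log2 of -0.22, with 4027 of 11445 above 0, from day 5 to day 25. Lowest were E2f3, of cell cycle entry (3.09 to 0.279 RPM), Slc13a4, Smad1, which relays signals of bone morphogenetic proteins (3.63 to 0.628), Dusp5, Bbx, Cux1, Pafah1b3, Sox6, Rxfp1 and the histone demethylase gene Kdm2a (5.27 to 1.30). Highest were Gpr165 (0.0908 to 2.49), Zc3h12d, Chst7, Spata19, Slc38a9, Necab1, Fcgr4, Yipf7, Pate8 and LOC115489517. Meiotic prophase (0.16, percentile 98.2) and maturation genes (0.06, 99.3) were high among random lists, while all 22 oocyte genes (-0.50, 27.02) and all 10 developmental transcription factors kept (-0.46, 7.38) were below 0. In windows of 5 kb the median was -0.03. Those highest were on chromosomes 16 (46250001 to 46255000, 0 to 3.67 RPM), 3 (102790001 to 102795000, 0 to 3.49) and over Cpne8 (0 to 3.16). The lowest were on chromosomes 2 (88645001 to 88650000, 2.00 to 0.0930) and 3 (12420001 to 12425000, 2.18 to 0.186). Over 69541 peaks, which the authors called in GV oocytes and which are therefore no independent evidence of a direction, the median was 0.726 RPKM at day 5 and 1.21 at day 25 (log2 0.58, inputs -0.11). That log2 was -0.0870 with the columns centred and -0.0316 with quantile scaling. Peaks over Lpar1 (0 to 2.04 RPKM) and Eya4 (0.0908 to 1.95) were among the highest, and those over Eif1b (4.90 to 1.069), Ccdc115 (4.36 to 1.069) and Ralgds (5.08 to 1.35) the lowest.

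H3K27me3 at promoters had a median of 0.44, with 2338 of 3301 above 0, and of -0.36 without the filter on RPM. Highest were Nbea, of synapse function (0.122 to 2.00 RPM), Arrdc4, the methyltransferase gene Smyd2 (0.609 to 4.70), Mark1, Zfp105, Ankmy2, Miga1, Slc19a2, Rai1 and Snx24. Lowest were Cltrn (2.31 to 0.182), the stem cell marker gene Prom1 (2.497 to 0.204), Kcng4, Prss56, Cpne7, Taf7l2, Mpp3, Ampd2, Gnat2 and the pancreas factor gene Pdx1 (2.13 to 0.295). All 17 developmental transcription factors kept were above 0 (0.46, percentile 3.89), such as Gata2 (2.13 to 5.40 RPM), as were the 3 meiotic prophase genes (1.41, 96.7), such as Syce1 (0.853 to 3.18). Granulosa markers had 0.63 (59.3), p53 targets 0.85 (93.5) and theca markers 0.06 (1.46). By windows the median was -0.98 in methylated and 0.43 in unmethylated domains, and -0.76 and 0.0812 without the filter. Windows over Atxn10 (chromosome 15, 85390001 to 85392000, 0 to 3.54 RPM) and Nid2 (0 to 3.09) were highest, and those over Msrb3 (3.41 to 0.0454), the stem cell receptor gene Lgr6 (2.19 to 0) and Svop (2.19 to 0) lowest.

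Technical libraries, made to set cell number and antibody amount, were compared by Pearson correlation of log2 RPM across windows with a mean of at least 1 RPM. H3K4me3 from the 2 libraries of 1000 ESC correlated at 0.406, and the library of 500 ESC correlated with them at -0.0263 and 0.0806, at 0.913 to 1.53 M reads. The inputs of 1000 and 500 ESC correlated at -0.0713, H3K4me3 of 1000 ESC with its input at -0.300 and that of 500 ESC with its own at -0.198. In oocytes H3K27me3 with 125 and 250 ng of antibody gave -0.125, 125 and 500 ng -0.161, and 250 and 500 ng -0.277. H3K27ac with 62.5 and 125 ng gave 0.398. Without the filter on RPM these were between 0.364 and 0.865. The filter takes windows by the mean of the same 2 libraries, which by itself lowers their correlation. The filtered values therefore do not show that libraries disagree. Windows are not independent replicates.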

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

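Tests chosen only after the result was seen were those of methylation loss at the 2 Zp3 domains, of both explanations for unmethylated domains, of a release of granulosa and stromal genes within oocytes, and the counts of splits.

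Mitochondrial CpG calls, which no comparison of the report uses, carried methylation above the 0.662% to 1.34% of the 10 bisulfite input libraries: 45.9%, 53.1% and 52.998% in Mll2 KO replicates 1, 2 and 3, and 46.7% and 54.5% in WT replicates 1 and 2. WT replicate 3 had 2.48%, and the cause was not tested.

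The 2 loci whose names stand in the genotype labels as positive, Zp3 for the DKO and Gdf9 for the Mll2 KO, each stood apart in the reads. Over the 2 Zp3 domains the DKO inputs held 2.67 times the CpG calls of WT (2.40 to 2.95 by library, 0.829 for other domains within 100 kb), 12.8 times over the unmethylated domain (10.5 to 15.5) and 1.67 times over the methylated one, beside H3K4me3 ratios of 12.5 and 9.10, which fits extra copies of Zp3 sequence as a candidate source of reads. Loss of DNA methylation is argued against at the unmethylated domain, where 0 of 21 calls were methylated in WT inputs (upper 95% limit 16.1%), while at the methylated domain (62.9% in WT inputs) it cannot be told apart from copies, as the same DKO libraries carry both. At the Gdf9 promoter the KO held 2.31 times the calls of WT, rank 2 of 13876 promoters (median 1.035, central 95% 0.795 to 1.34), which fits extra copies of Gdf9 sequence as a candidate source of its methylated calls. A change at the native Gdf9 locus cannot be told apart from this: the lowest KO library had 2.19 times the WT calls, a value set beforehand to count against it, but added and native copies are pooled in the calls, so that bound was wrong.

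Methylation of unmethylated domains differed within genotypes, at 17.5%, 14.8% and 10.5% in the KO and 13.9%, 15.5% and 8.13% in the WT libraries. Incomplete conversion of whole libraries is argued against, since promoters of developmental transcription factors ranged over 0.670 points where the domains ranged over 9.34. DNA of other cell types, which methylate germline genes, is a candidate source as a hypothesis. Over the 6 libraries the domains correlated with the 17 meiotic prophase promoters tested (15 of these genes have at least 1 RPKM of RNA in the oocytes), with r = 0.909 (exact permutation p = 0.0167, adjusted p = 0.0278), rho = 0.886 (p = 0.0333, adjusted p = 0.0556), and r = 0.917 without the 2 farthest libraries, among 5 relations: the others were X-linked (r = 0.995, adjusted p = 0.00694), oocyte (0.978, 0.00694), housekeeping (0.884, 0.0278, but r = 0.168 without the 2 farthest) and developmental transcription factor promoters (0.566, 0.264). Differences between pools of oocytes would give such correlations too and stay open, untested, as does whatever set mitochondrial calls to 2.48% in WT replicate 3, the library lowest in the domains, and to 45.9% to 54.5% in the others, of which KO replicate 1 was lowest there and highest in the domains.

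Markers of granulosa and stromal cells were higher in the KO RNA column. Of 20 markers under 1 RPKM in WT, 55.0% reached 1 RPKM in KO, against 13.9% of 3978 other genes (a ratio of 3.97), while 4 of the 24 markers with a value were at 1 RPKM or more in WT oocytes. Levels in KO argue against granulosa cells as the whole source, but only weakly, since the markers were split. Fshr (12.4 RPKM), Gja1 (11.05) and Inha (10.3) stood beside Amh at 0, Foxl2 at 0.485, Inhba at 0.271 and Nr5a1 at 0.104. Such cells hold Amh in plenty, but Amh was listed at 0 in WT too, so whether it could be measured is open. Gatm (0.495 in WT to 3.59 in KO), Hsd17b1 (0.202 to 1.51), Amhr2 (0.184 to 1.14) and Foxl2 (from 0.0261) were higher in KO. Col1a2 (7.05) and Col1a1 (6.92) led the stromal genes. The labels describe oocytes collected by hand and washed, which removes other cells, and no sort. RNA of other ovarian cells and a release of these genes in the KO oocytes themselves cannot be told apart, because either gives that share, the 4 oocytes form 1 column, and promoters of the 2 lists changed by a median of 0.349 points.

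For tiles (5080 called), promoters (377) and gene bodies (5706), 1 of the 10 splits of the 6 PBAT libraries into 3 and 3, the real one, gave as many calls, and the highest other count was 0 in each. The 10 splits are too few for a share under 0.05.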

How the results depend on the processing

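All alternatives were chosen beforehand except the classes of domain for Dnmt3ab, the promoters of H3K27ac and H3K27me3, the Dnmt3ab domain ratio without the 2 Zp3 domains (log2 0.47), growth libraries over positions with at least 3 calls, and RNA lists of every gene with a value matched on the WT level, chosen after seeing the data. There were 1600 values of 238 named or listed results under alternatives. Of these 1411 kept their direction and their side of the threshold, or moved by less than a set tolerance. For ChIP medians the tolerance was 0.58 on the log2 scale. Direction held but the call was lost in 81 and gained in 4. Another 96, such as medians, correlations and called counts, moved by more than the tolerance. In all 33 had the opposite sign: the 8 listed next, 20 of those that moved (medians and technical correlations of ChIP without a filter or scaled, chiefly) and 5 close to 0. For named promoters 277 of 301 held (15 lost, 2 gained), for gene bodies 561 of 613 (50 lost, 2 gained), for Mll2 tiles 66 of 66, for Dnmt3ab tiles 50 of 66 (16 lost) and for RNA 316 of 344 (28 moved). Methylated domains differed by -7.58 to -6.44 points, and all calls by -3.48 to -0.535, when each library was left out. Where a result changed below, the cause was not tested unless stated. Sign changed for unmethylated domains (-0.488 without WT replicate 3, range -0.488 to 3.60) and for promoters that were not called: Dnmt3a (-1.71 without KO replicate 1 and -2.003 without WT replicate 3, range -2.003 to 5.58), Dnmt3l (-0.411 and -1.12 without the same libraries, range -1.12 to 4.13) and Kmt2b (1.10 without KO replicate 2, 0.0746 without KO replicate 3 and 1.48 without WT replicate 2, range -1.47 to 1.48).

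Called counts with each library left out, and so with fewer samples, ranged from 1583 to 7540 for tiles, 199 to 302 for promoters, 3268 to 6542 for gene bodies and 2513 to 4460 for Dnmt3ab tiles. Leaving out a WT library of Dnmt3ab left 1 WT sample, assumed to vary like DKO. A replicate block gave 31583 Mll2 and 1914 Dnmt3ab tiles. At 10 points or more there were 251 promoters and 1682 gene bodies, by the added condition itself, and limma gave 219 promoters. Over positions with at least 3 calls, 5887 to 21345 per library, Dnmt3ab differed by -8.78 points over all calls, -57.0 in methylated and -2.42 in unmethylated domains. At least 10 calls gave 11741 Dnmt3ab tiles and at least 50 gave 218, since more or fewer tiles were tested. Granulosa markers in RNA had a median log2 of 1.79 with a pseudocount of 0.1 RPKM and 0.49 without a filter, and theca markers 2.99 with that pseudocount. As means over tiles, methylation was 2.53% in unmethylated domains at day 10. By the same means day 15 had 25.0%, 67.5% and 4.39% over all calls, methylated and unmethylated domains, day 25 38.7%, 89.8% and 9.44%, and day 5 4.26%, 3.96% and 2.92%. Over positions with at least 3 calls, day 5 had 14.7%, 7.73% and 15.2%, day 15 17.6%, 47.9% and 13.9%, day 25 27.9%, 74.0% and 20.8%, and day 10 10.6% over all calls and 10.2% in unmethylated domains. By median density the log2 ratio of H3K4me3 in methylated to unmethylated domains at day 10 was 0.00. Without a filter, the median log2 of windows for H3K4me3 was -0.0553 (day 10 over 5), 0.13 (15 over 10), -0.12 (25 over 15) and -0.17 (25 over 5), and -0.0895 for H3K27me3. With each column centred on its median log2 over all windows, and with the filter, they were 0.87 (10 over 5), 1.22 (25 over 5) and 0.89 (H3K27me3), and quantile scaling gave 0.00662 (15 over 10) and 0.00 (25 over 15). Centring and quantile scaling gave -0.0870 and -0.0316 at H3K27ac peaks and -0.12 and -0.0143 at H3K4me3 promoters, since both take out a shift of the whole column.

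Technical correlations without a filter were 0.364 and 0.375 (500 ESC with each of 1000 ESC), 0.865 (inputs), 0.392 and 0.396 (H3K4me3 with input, 1000 and 500 ESC), 0.484, 0.485 and 0.437 (H3K27me3, 125 with 250, 125 with 500 and 250 with 500 ng) and 0.818 (H3K27ac). As log2(RPM + 1) the ESC libraries gave 0.692, 0.288 and 0.393. Not run, because each group had 1 pooled column, were leaving out libraries or oocytes, a block, the antibody amount as a term, adding the titration libraries and 250 ng alone. A minimum log2 of 1 had no calls to apply to, and no DKO input column was at hand to subtract; the Mll2 H3K4me3 ChIP was not analysed here. No paired analysis was possible because the pooled ChIP columns hold no separate libraries. At the depth of these libraries, simulated falls of 10 points were recovered in 4.48% at promoters and 0% in Dnmt3ab tiles. These falls were made only in regions of intermediate to high methylation. Depth was not varied on its own.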

Other observations

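Tests chosen only after the result was seen were those of gene body methylation against RNA and the values given next at promoters.

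Promoter marks followed RNA of WT oocytes in a way that differed by mark. Across 14237 promoters, H3K4me3 had a Spearman correlation with RNA of WT oocytes at day 21 of 0.433 at day 5, 0.429 at day 10, 0.343 at day 15 and 0.350 at day 25, without a test. H3K27ac, a mark of active promoters and enhancers, had 0.370 at day 5 and 0.431 at day 25. H3K27me3, deposited by Polycomb, had -0.368 and -0.399. The inputs lay between -0.0996 and -0.0204. Signal density at promoter windows over that elsewhere was 3.04 for H3K4me3 at day 5, 5.86 at day 10, 3.34 at day 15 and 4.096 at day 25, against 1.008 for H3K27me3 at day 25. Promoters are not independent replicates. Outside promoter windows, H3K4me3 density in unmethylated domains was 0.404 RPM per kb at day 5 and 0.529 at day 25, and in methylated domains 0.437 and 0.156.

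A hypothesis is that loss of transcription in KO oocytes goes with loss of gene body methylation, since oocytes methylate transcribed units. Among gene bodies at 50% or more in WT, the 46 genes with an RNA log2 ratio of -2 or less had a median change of -47.8 points, and 40 of them were called. The 6855 genes with RNA within 0.5 of 0 had -5.14 points, and the 99 with a log2 of 1 or more -3.82. Those 99 had a median of 71.4% in WT, which limits a gain, so they do not show whether higher RNA goes with one. Without the limit of 50%, the 41 genes at 2 or more had a median of 2.30 points, with 8 called up and 1 down. The larger falls at -2 or less fit the hypothesis in the test run. But methylation and RNA came from the same genotype comparison, RNA had 1 column per genotype, and the order of the 2 changes was not tested.

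A further hypothesis is that, within unmethylated domains, tiles with more H3K4me3 in oocytes of the growth course gain more methylation in the KO. Those oocytes are not the Mll2 WT, whose H3K4me3 was not analysed here. The Spearman correlation of the change with H3K4me3 at day 25 across 106533 tiles was 0.176, between the bounds set for and against it, so the test leaves it undecided and it may or may not hold. It was 0.132 at day 5, 0.151 at day 10 and 0.165 at day 15, and 0.0595 to 0.131 for inputs. The 446 tiles that rose had a median of 0.965 RPM at day 25, and the 106052 not called 0.721. Other marks gave similar contrasts, so the relation is not specific to H3K4me3: at day 25 H3K27ac had a correlation of 0.1599, and H3K27me3 0.0994 with medians of 1.73 and 1.071 RPM. Neighbouring tiles are not independent.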
